A study of Mus musculus with 2 samples.

How the data were processed

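Single-cell RNA was measured in 2 libraries of GFP-sorted mouse tumour cells, 1 from vehicle-treated and 1 from cisplatin-treated animals, with 5000 cells loaded per library per the labels. Tumours were dissociated with collagenase IV and DNase, live GFP-positive cells were sorted and the 10x Genomics platform was used, per the labels' protocols. The deposited values are raw UMI counts per gene and barcode with no normalization, per the file headers, and Cell Ranger 2.0.2 and the mm10 genome are named in the submitters' processing notes without their roles. The lowest total of a barcode was 2478 UMIs in vehicle and 1892 in cisplatin, so empty droplets had been removed before the counts were deposited. The matrices held 28692 genes. Coordinates come from GENCODE M21 (GRCm38), in which 28339 gene identifiers were found and 353 were not.

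Barcodes with under 500 detected genes or over 10% mitochondrial UMIs were removed, 54 from vehicle and 36 from cisplatin. Barcode totals reached 42873 and 82540 UMIs. Scrublet, as run in scanpy 1.11.5 with an expected doublet rate of 0.06, marked 1 vehicle barcode (0.0272%) and 6 cisplatin barcodes (0.142%). That was below the 0.5% set as the minimum for the method to count as having worked, so no barcode was removed as a doublet. Both libraries were clustered together without batch integration, since library and treatment are the same variable. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 were used (igraph 0.11.9, seed 1). The members of 14 readout lists, mitochondrial and ribosomal protein genes, Xist and Y-linked genes were left out of the clustering genes.

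Clusters were named from 24 marker sets. A set needed at least 3 markers at 100 CPM or more with 20 UMIs or more in the cluster. The non-neuroendocrine tumour name was open only to clusters with under 3 neuroendocrine markers at that level. Barcodes with at least 3 markers of another cell type, each found in under 2% of barcodes, were left out of the tumour class. The thresholds for naming and the step on barcodes with other markers were chosen after seeing the data. Clusters that met no criterion stayed unnamed.

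UMIs were summed per gene over the cells of a class in each library, scaled to CPM and compared as a log2 ratio with 1 CPM added. A gene counted as measured with at least 50 UMIs over both libraries, and a list member as higher or lower with a 1.5-fold difference in CPM. Intervals are exact 95%, Poisson for sums and Clopper-Pearson for shares, and the limit given for a count of 0 is 3 counts of the total. For shares of cells with a UMI, each cell was thinned to 3000 UMIs and cells below that were left out. A cycling cell had at least 2 UMIs over 10 mitotic genes. Each of 22 gene lists was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched in 20 bins of expression. The lists cover neuroendocrine and non-neuroendocrine genes, YAP targets, the Hippo and Notch pathways, subtype factors, p53 targets, DNA repair, apoptosis, platinum handling, G1/S, G2 and mitosis, interferon, MHC class I and class II, mesenchymal transition, epithelial genes, dissociation stress, hypoxia and glycolysis, the unfolded protein response and oxidative phosphorylation. Another list, and some genes that the naming rule takes, are not reported here.

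Genes were named in the text by a rule. It took the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 20 CPM, without mitochondrial, ribosomal protein, haemoglobin, predicted and Y-linked genes and Xist. It also took up to 4 measured members of each list with the largest absolute ratio, the deleted genes, the subtype factors, Yap1, Wwtr1, Notch2, Hes1, Rest, Calca, Chga, Vim, Xist and Ddx3y. Other members that passed the 1.5-fold limit or are well-known members of a list (Cdkn1a, Mdm2, Ifit1, Insm1, Mcl1 and the like) were chosen after their values were seen. The lists, the markers, the naming rule, the comparisons and the alternatives for filters, resolution, scaling, pseudocount, floor, fold and depth were fixed before the data were examined. The pairs of clusters, the removal of cluster 8, the removal of the trend with transcript length, and the other added alternatives were chosen after seeing the data. Each pair joined a vehicle and a cisplatin cluster taken to be of like cell cycle phase.

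Other scalings were TMM (edgeR 4.0.16) and median-of-ratios size factors (DESeq2 1.42.0) in R 4.3.3. The remaining steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 (lowess trends) and matplotlib 3.10.9. The steps were tested on simulated data. With the depth of the tumour-like class, 99.0% of genes changed 2-fold were called (199 changed among 13291 genes) and 0.8% of unchanged genes were called. With the depth of clusters 3 and 4, 91.8% of genes changed 2-fold were called (196 among 10227 genes) and 2.93% of unchanged genes. Of 200 unchanged lists, 2.5% and 3.5% lay outside the central 95% of random lists. Clustering returned 4 of 4 simulated groups with an adjusted Rand index of 0.996. These groups were drawn, at equal size and depth, from the summed profiles of clusters that the same method had already separated. Their recovery therefore does not test whether the clusters in the data are real. The simulated counts held counting error only, so none of these rates covers variation between libraries. No test across cells was made, since cells of 1 library are not replicates.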

Results

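Small cell lung cancer is a fast-growing neuroendocrine tumour of the lung that is treated with platinum drugs. The cells came from lung tumours of mice with floxed tumour suppressor alleles, Rb1 and Trp53 among them, and a tamoxifen-inducible Cre recombinase at the CGRP (Calca) locus. A Rosa26 mTmG reporter switches a cell from membrane Tomato to membrane GFP after Cre recombination, and live GFP-positive cells were sorted before droplet capture. Single-cell RNA was counted in 1 library from saline-treated (vehicle) mice and 1 library from mice given cisplatin, a DNA-crosslinking drug, at 5 mg per kg every 4 days for 2 weeks. The library protocol names cisplatin with etoposide for the treated tumours and the sample title names chemotherapy, so whether etoposide was also given is open. The number of animals behind each library was not given in the sources used here. The series title names YAP, variety among cells within the tumour and sensitivity to chemotherapy, so the comparisons ask how the make-up and the expression of the sorted cells differed between the libraries, with YAP and its partners among the readouts.

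The vehicle library held 3726 barcodes and 32519922 unique molecular identifiers (UMIs), with a median of 8168 UMIs per barcode. The cisplatin library held 4254 barcodes and 28777462 UMIs, with a median of 5925. After the filters on detected genes and mitochondrial share, 3672 vehicle and 4218 cisplatin barcodes remained. With 1 library per group there was no replicate check and no test: values are given side by side, and the exact 95% intervals cover counting error only. Levels are UMIs summed over cells and scaled to the total of the same cells, in CPM, and log2 ratios are cisplatin over vehicle after adding 1 CPM.

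The deleted genes come first. In neuroendocrine tumour-like cells, Rb1 (the retinoblastoma cell cycle brake; GRCm38 chromosome 14, 73183673 to 73325822) was at 18.1 CPM in vehicle (16.6 to 19.6) and 13 CPM in cisplatin (11.7 to 14.5). Trp53, which encodes p53 (chromosome 11, 69580359 to 69591873), was at 71.2 CPM (68.2 to 74.3) and 80.9 CPM (77.5 to 84.3). Which exons the floxed alleles remove was not given in the sources used here, and tags near the 3' end of a transcript lie outside many such deletions, so these levels check neither the deletion nor the labels.

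Almost all kept cells of both libraries were neuroendocrine tumour-like. That class made up 94.4% of the vehicle library (3465 of 3672 barcodes; 93.6 to 95.1%) and 95.2% of the cisplatin library (4017 of 4218; 94.5 to 95.9%). No cluster met the criteria for non-neuroendocrine tumour-like or tuft-like cells, so the planned comparison of neuroendocrine with non-neuroendocrine cells could not be made. The non-neuroendocrine name was barred to any cluster with at least 3 neuroendocrine markers at 100 CPM, whether expressed or from free RNA. The lack of such a cluster is therefore set in part by the naming rule. Non-neuroendocrine or tuft cells inside another cluster, or in the unnamed cluster 6, are not excluded. The sort for GFP-positive cells sets these shares in part, since recombination started from Calca-expressing cells.

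Inside the class, different clusters held the cells of each library: clusters 0, 1 and 3 held most vehicle cells, and clusters 2, 4, 5 and 8 most cisplatin cells. Cluster 1 held 58.2% of the vehicle barcodes and cluster 5 held 44.7% of the cisplatin barcodes, while each held under 1% of the other library (0.664% and 0.463%). Cluster 8, led by Ceacam10, Pnoc, Sst, Hoxb8, Hhex and Isl1, held 754 cisplatin cells (17.9%; 16.7 to 19.1%) and 17 vehicle cells (0.463%; 0.270 to 0.740%). Cluster 7, led by the interferon-response genes Ifit3, Isg15 and Rsad2, held 1.68% of cisplatin (1.32 to 2.12%) and 0.545% of vehicle barcodes (0.333 to 0.840%). Cluster 6, led by the stress-response genes Nupr1, Trib3 and Ddit3 together with Dcn, was left without a type and was the only cluster spread evenly, with 4.93% of vehicle (4.25 to 5.68%) and 4.60% of cisplatin barcodes (3.99 to 5.28%). A cluster that comes mostly from 1 library can reflect that library and not a cell type, and cluster 8 was kept in the class because its markers are neuroendocrine.

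**Figure D1:**
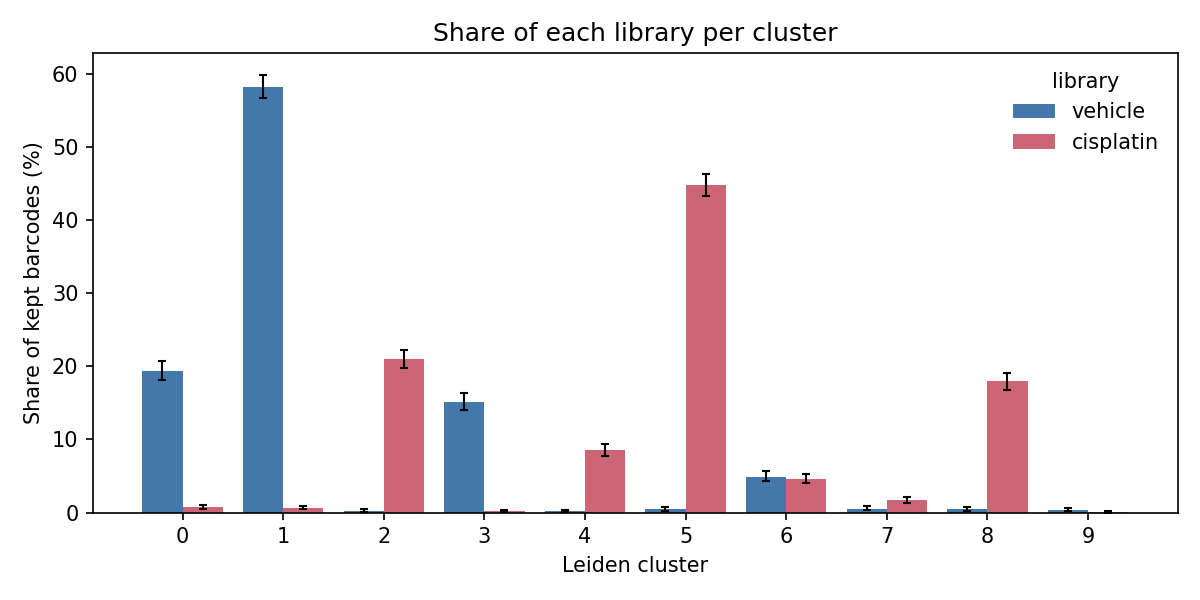
Share of the kept barcodes of the vehicle library (blue) and of the cisplatin library (red) in each of the 10 clusters, in percent, with exact 95% binomial intervals as error bars. Cluster 6 holds a similar share of both libraries (4.93% and 4.60%), while cluster 8 holds 17.9% of the cisplatin and 0.463% of the vehicle library.

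Within neuroendocrine tumour-like cells, Pyy, Meg3, Ccl27a and Rprm were among the genes with the highest ratios and Igf2 had the lowest. Pyy, the gut hormone peptide YY, was at 1.51 CPM in vehicle (1.11 to 2.02) and 77.6 CPM in cisplatin (74.3 to 81.0). The maternally expressed noncoding RNA Meg3 was at 25.7 CPM (23.9 to 27.6) and 572 CPM (563 to 581), the chemokine Ccl27a at 1.08 CPM (0.746 to 1.52) and 59.4 CPM (56.6 to 62.4), and Rprm, which encodes the G2 arrest mediator Reprimo, at 1.25 CPM (0.883 to 1.71) and 55.6 CPM (52.9 to 58.5). Thy1 (log2 ratio 4.72) and Fam183b (4.30) were also among the 12 highest, and the others, Pnoc, Ceacam10, Sfrp5, Hoxb8, Gfra4 and Hhex, lead cluster 8. Ceacam10 was also higher in each pair of like clusters, which leave cluster 8 out. It was at 2.28 and 46.6 CPM in clusters 1 and 5, 3.04 and 37.8 CPM in 3 and 4, and 2.45 and 48.5 CPM in 0 and 2. At the low end stood Igf2, the paternally expressed insulin-like growth factor 2, at 183 CPM (178 to 188) and 20.6 CPM (19 to 22.4), and the replication-dependent histone genes Hist1h1e at 93.3 CPM (89.9 to 96.8) and 11.3 CPM (10.1 to 12.6), Hist1h1b (log2 ratio -2.55), Hist1h2ae (-2.55) and Hist1h2ak (-2.12).

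The other genes with the lowest ratios were Mgst1 (log2 ratio -2.19), a membrane-bound glutathione transferase, RP23-477O13.1 (-2.06), the synaptic organiser Cbln4 (-2.06), Slfn9 (-2.03), the growth factor Nrg2 (-1.89), the orphan receptor Gpr37l1 (-1.84) and the secreted phospholipase Pla2g2f (-1.82). When cluster 8 was left out, a step chosen after seeing the data, Rprm was the highest gene at 1.22 CPM in vehicle and 68.3 CPM in cisplatin, Meg3 was at 14.9 and 145 CPM, and Hist1h1e and Igf2 stayed lowest, with log2 ratios of -2.98 and -2.78. Il1rn, the interleukin-1 receptor antagonist, at 47.2 CPM in vehicle and 193 CPM in cisplatin, and the secreted protease Klk1, at 110 and 463 CPM, then joined the 12 highest. Canonical histone transcripts mostly lack a poly(A) tail, so a 3' tag method captures only part of them, and reads of near-identical histone genes cannot always be assigned.

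The median log2 ratio of the 13286 genes with at least 50 UMIs in this class was -0.17. Of these, 1077 were at least 1.5-fold higher and 2910 at least 1.5-fold lower in the cisplatin library. The scaling moved this split: scaling by trimmed means of M values (TMM) moved the median by 0.12 to -0.05, with 1447 genes higher and 2039 lower, and median-of-ratios size factors moved it by 0.15 to -0.03, with 1567 and 1885. The median of the G2 and mitosis list, -0.05 in CPM, was above 0 under both of these scalings, as were those of MHC class II (-0.03) and mesenchymal transition (-0.07). Medians of gene lists are therefore given relative to the median of all measured genes, and counts of members refer to a 1.5-fold difference in CPM. Where they differ, the counts relative to the median of all genes stand beside them, since a one-sided count in CPM can come from that median alone. Random lists of like expression can have another median than all genes, as for the neuroendocrine list (0.04, against -0.17). A list can therefore lie above the median of all genes and still at a low percentile.

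Yap1 was at a low level in both libraries. Yap1, the transcriptional coactivator of the Hippo pathway (chromosome 9, 7931999 to 8004596), had 30 UMIs among 3465 vehicle cells and 19 among 4017 cisplatin cells of the class, or 0.985 CPM (0.665 to 1.41) and 0.699 CPM (0.421 to 1.09), a difference not detectable at this depth. In cells thinned to 3000 UMIs, 10 of 3326 vehicle cells (0.301%; 0.144 to 0.552%) and 4 of 3672 cisplatin cells (0.109%; 0.030 to 0.279%) had a Yap1 UMI, against 0.866% and 0.473% unthinned. Its paralog Wwtr1 (TAZ) had 0 and 3 UMIs. The background for such a share was a UMI of Yap1 in 0 of 10 T cell-marked barcodes (up to 30.9%; median depth 4404 UMIs) and in 0 of 6 endothelial-marked barcodes (up to 45.9%; median depth 6612.5 UMIs), beside medians of 8205.5 and 5940.5 UMIs over all kept barcodes. Over all barcodes with markers of other cell types, 1 of 33 had a Yap1 UMI (3.03%; 0.077 to 15.8%; median depth 7097 UMIs), unthinned. These are too few to separate expression in tumour cells from free RNA. Wwtr1 had a UMI in 2 of the 6 endothelial-marked barcodes, and whether these other types lack Yap1 was not checked, so they are not a clean background. Of 14 measured YAP target genes, 6 were lower and 1 was higher, with a list median 0.27 below that of all genes. Relative to all genes 5 were lower and 2 higher, and with the trend on transcript length removed 2 were lower and 1 higher. Amotl1 (5.45 and 1.73 CPM), Crim1 (17.4 and 7.80 CPM) and Asap1 (32.0 and 16.2 CPM) were lower, and Cyr61, a classic YAP target, was higher (8.41 and 12.6 CPM). The list median lay at percentile 7.09 of 10000 random lists of like expression, and at percentile 46.9 without cluster 8.

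Among 13 measured Hippo pathway genes, 5 were lower and 0 higher, with a median 0.27 below that of all genes (percentile 7.19). Relative to all genes 3 were lower and 1 higher. Tead2, a DNA-binding partner of YAP, was at 6.08 CPM in vehicle and 2.54 CPM in cisplatin, and the scaffold gene Sav1 at 20.4 and 11.7 CPM. Of 15 Notch pathway genes, 3 were higher and 5 lower, with a median 0.06 below that of all genes (percentile 40.9), and relative to all genes 3 were higher and 3 lower. Hes1, a repressor induced by Notch signalling, was at 28.2 CPM in vehicle (26.4 to 30.2) and 90.2 CPM in cisplatin (86.6 to 93.8). It was detected in 7.01% of thinned vehicle cells and 18.2% of thinned cisplatin cells (16.8% and 29.9% unthinned). In the small immune cluster 9 (median depth 3380 UMIs in vehicle) the thinned vehicle share for Hes1 was 8.33% (1 of 12; 0.211 to 38.5%), and in cisplatin (median depth 9245 UMIs) 2 of 2 had a UMI (15.8 to 100%); these are too few to set a background. Hes1 was also higher in cisplatin in each pair of like clusters (22.1 and 65.4 CPM in clusters 1 and 5, 36.1 and 155 CPM in 3 and 4, 34.7 and 114 CPM in 0 and 2) and in cluster 6 (73.2 and 172 CPM). The receptor Notch2 was at 0.526 CPM (0.30 to 0.853) and 3.97 CPM (3.26 to 4.80), and at 0.529 CPM (0.302 to 0.859) and 2.09 CPM (1.52 to 2.81) without cluster 8, which held 55 of the 96 cisplatin cells with a UMI of Notch2. Thinned, 0.120% and 0.980% of cells had one, and 0.121% and 0.506% without cluster 8. In cluster 9, 1 of 15 vehicle barcodes had a Notch2 UMI unthinned and 0 of 12 thinned, too few to set a background. The ligands Dll4 (25.4 and 8.09 CPM) and Jag2 (9.23 and 3.46 CPM) were lower.

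Neuroendocrine genes differed in both directions. Of 23 measured members, 9 were higher and 3 lower (10 and 2 relative to all genes), with a median 0.49 above that of all genes (percentile 99.8). Scg2 (secretogranin 2) was at 184 and 1931 CPM, Resp18 at 1719 and 3917 CPM, Insm1, a neuroendocrine transcription factor, at 519 and 954 CPM, and Chga (chromogranin A) at 375 and 727 CPM. Without cluster 8 the list median was 0.15 above that of all genes (percentile 33.8), with 3 higher and 2 lower (6 and 1 relative to all genes). Scg2 was then at 147 and 210 CPM, Chga at 369 and 317 CPM, Resp18 at 1721 and 4031 CPM and Insm1 at 518 and 966 CPM. Of 12 measured non-neuroendocrine genes, 7 were higher and 1 lower, with a median 0.74 above that of all genes, above all 10000 random lists, and 0.33 above it without cluster 8 (percentile 98.2). Vim (vimentin) was at 0.690 and 15.5 CPM and Anxa2 at 27.1 and 94.2 CPM. Without cluster 8, Vim was at 0.430 CPM (0.229 to 0.735) and 1.38 CPM (0.923 to 1.98) and Anxa2 at 26.2 and 52.0 CPM. Among marker sets of normal lung epithelium, the alveolar type 2 and club or secretory sums were higher, each mostly through 1 gene. That of alveolar type 2 cells was at 56.4 and 205 CPM, with Sftpc at 20.5 and 167 CPM (81.8% of the set in cisplatin). That of club or secretory cells was at 288 and 544 CPM, with Scgb1a1 at 165 and 463 CPM (57.2% and 85.2% of the set). The ciliated set was at 60.2 and 86.2 CPM, the alveolar type 1 set at 10.9 and 10.2 CPM and the basal set at 7.62 and 4.12 CPM. Without cluster 8 the log2 ratio of Sftpc was 0.17 and that of Scgb1a1 1.58. In the pairs of like clusters, chosen after seeing the data, the neuroendocrine list median lay 0.09 above that of all genes (cluster 1 in vehicle and 5 in cisplatin; percentile 10.5), 0.01 below it (3 and 4; percentile 2.13) and 0.29 above it (0 and 2; percentile 91.5), and Chga differed by less than 1.5-fold in each pair (401 and 364 CPM, 429 and 339 CPM, 253 and 239 CPM).

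Among factors that define subtypes of this cancer, the 5 measured had a median 0.30 below that of all genes (percentile 5.30). Neurod1 had 0 and 1 UMIs, Pou2f3 0 in both libraries (up to 0.0985 and 0.110 CPM), and Atoh1 1 and 0. Mycl was at 62.7 and 44.5 CPM, Mycn at 7.10 and 6.47 CPM, Myc at 19.7 and 22.3 CPM, and Nfib at 326 and 235 CPM. Calca, whose locus carries the Cre, had 15 and 11 UMIs, and Rest, a repressor of neuronal genes, 8 and 6. Ddx3y, on the Y chromosome, was at 45.1 and 58.1 CPM and Xist, expressed from the inactive X, at 0.526 and 1.21 CPM.

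Most p53 target genes differed by less than 1.5-fold. Of 19 measured, 2 were higher and 0 lower (3 and 0 relative to all genes), with a median 0.21 above that of all genes (percentile 92.4; 99.3 without cluster 8). Plk2 was at 24.0 and 45.9 CPM and Eda2r at 1.45 and 2.54 CPM, while Cdkn1a, which encodes the cell cycle inhibitor p21, was at 424 and 452 CPM and Mdm2 at 68.2 and 61.6 CPM. Of 20 DNA repair genes, 4 were lower and 0 higher, with a median 0.12 below that of all genes (percentile 27.7). Relative to all genes 2 were lower and 2 higher, and with the length trend removed 0 were lower and 1 higher. Those lower in CPM included Brca2 (34.4 and 18.4 CPM) and Rev3l (54.9 and 30.8 CPM), the catalytic subunit of a translesion polymerase. Of 16 apoptosis genes, 5 were lower and 0 higher, with a median 0.06 below that of all genes (percentile 41.2). Mcl1 was at 65.8 and 42.0 CPM. Relative to all genes 2 apoptosis genes were lower, and with the length trend removed 1 was lower, with 0 higher in both. Of 16 genes of platinum handling, 5 were higher and 3 lower (6 and 2 relative to all genes), with a median 0.28 above that of all genes (percentile 96.6). Without cluster 8, 2 of 14 were higher and 2 lower (4 and 2 relative to all genes), with a median 0.17 above that of all genes (percentile 83.9). The metal-binding metallothioneins Mt1 (742 and 1902 CPM) and Mt2 (797 and 1378 CPM) were higher, as was the efflux pump Abcg2 (0.427 and 6.18 CPM), and the transporter Abcc1 was lower (9.76 and 4.60 CPM). Without cluster 8 these were at 718 and 1318 CPM (Mt1), 774 and 1073 CPM (Mt2), 0.331 and 0.760 CPM (Abcg2) and 9.76 and 4.56 CPM (Abcc1).

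Cell cycle genes as groups differed little over the whole class, but not in the same direction in each pair of like clusters. The clusters of each pair were taken to be of like cell cycle phase without a measured match, so these directions also depend on how well the phases match. Of 52 genes of G2 and mitosis, 2 were higher and 3 lower (5 and 2 relative to all genes), and their median was 0.12 above that of all genes (percentile 50.7; 97.9 without cluster 8). Of 41 genes of the G1/S transition, 1 was higher and 7 lower, with a median 0.03 below that of all genes (percentile 10.9). Relative to all genes 3 were higher and 4 lower, and with the length trend removed 2 were higher and 1 lower. In clusters 1 and 5, 0 G1/S genes were higher and 11 lower (0 and 8 relative to all genes; percentile 0.60), in 3 and 4 there were 1 and 6 (2 and 2 relative to all genes; percentile 0.20), and in 0 and 2 there were 13 and 0 (15 and 0; percentile 100). For G2 and mitosis these were 0 and 6 (2 and 6 relative to all genes; percentile 99.1), 6 and 6 (10 and 3; percentile 89.3), and 0 and 13 (1 and 6; below all random lists), and in cluster 6 there were 24 and 3 by either count (percentile 100). The proliferation marker Mki67 was at 236 CPM (230 to 241) in vehicle and 92.0 CPM (88.5 to 95.7) in cisplatin, while Cks2, a subunit of cyclin-dependent kinases, was at 354 and 611 CPM. The share of thinned cells with at least 2 UMIs over 10 mitotic genes was 41.9% in vehicle (1392 of 3326; 40.2 to 43.6%) and 44.4% in cisplatin (1629 of 3672; 42.7 to 46.0%). Unthinned, the order turned, with 64.6% and 57.6%. Thinning left out 139 vehicle and 345 cisplatin cells. In cluster 6 the thinned shares were 23.7% and 39.9%, but the unthinned ones were 53.6% and 54.6%, and free mitotic RNA was not separated from expression.

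Genes of the interferon response and of stress stood above the other genes. Of 21 interferon genes, 7 were higher and 2 lower (8 and 0 relative to all genes), with a median 0.40 above that of all genes, above all 10000 random lists. The chemokine Cxcl10 was at 2.83 CPM (2.26 to 3.49) and 19.5 CPM (17.8 to 21.2), Ifit3 at 2.56 and 16.4 CPM, Ifit1 at 45.0 and 114 CPM, and Isg15 at 33.8 and 77.3 CPM. A large part of these UMIs lay in the small cluster 7, which had 52 and 361 UMIs of Ifit3 against 78 and 447 in the class, 33 and 243 of Cxcl10 against 86 and 529, and 195 and 1184 of Ifit1 against 1371 and 3094. Within cluster 7, Ifit3 was at 266 CPM (198 to 348) and 637 CPM (573 to 706). The interferon median was not higher in each pair of like clusters. Relative to all genes it was 0.14 above in clusters 1 and 5, 0.09 below in clusters 3 and 4, and 0.27 above in clusters 0 and 2. Of 11 members tested in all 3 pairs, 0 were higher in all of them. That count decides nothing, since only 101 of all 5604 genes tested were higher in all 3. Of 12 genes of the major histocompatibility complex (MHC) class I pathway, 1 was higher and 2 lower (1 and 1 relative to all genes), with a median 0.29 above that of all genes (percentile 91.1), and B2m, the light chain of class I molecules, was at 842 and 1619 CPM (838 and 1224 CPM without cluster 8). Of 5 MHC class II genes, 1 was higher and 0 lower (median 0.14 above that of all genes, percentile 65.5). Of 18 genes that respond to tissue dissociation, 5 were higher and 2 lower (6 and 2 relative to all genes), with a median 0.54 above that of all genes (percentile 99.9) and 0.72, 0.58 and 0.58 above in the 3 pairs, including the heat shock gene Hspa1a at 154 and 459 CPM, while Fosb was at 231 and 72.2 CPM. Of 14 genes of the unfolded protein response, 4 were higher and 0 lower (6 and 0 relative to all genes), with a median 0.46 above that of all genes (percentile 99.3), including Pdia4, a disulfide isomerase of the endoplasmic reticulum, at 61.4 and 125 CPM. In the pair of clusters 0 and 2 that median was 0.07 below that of all genes. In cluster 6, which lies outside the class and is led by Trib3 and Ddit3, 0 were higher and 6 lower (percentile 0.27). Over all kept barcodes, which include cluster 6, 2 were higher and 0 lower (5 and 0 relative to all genes). The median there was 0.29 above that of all genes (percentile 87.6, and 68.9 with the length trend removed).

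The remaining lists lay between percentiles 20.8 and 75.6 of the matched random lists. Of 16 hypoxia and glycolysis genes, 2 were higher and 4 lower (2 and 2 relative to all genes), with a median 0.05 below that of all genes (percentile 40.6), and the oxygen sensor Egln3 was at 32.6 and 10.4 CPM. Of 18 genes of oxidative phosphorylation, 2 were higher and 0 lower (0.18 above, percentile 20.8). Of 13 epithelial genes, 4 were lower and 0 higher (0.23 above, percentile 72.6), including the adhesion gene Cdh1 at 291 and 184 CPM. Relative to all genes 1 epithelial gene was lower and 1 higher, and with the length trend removed 1 was lower and 0 higher. Of 7 measured mesenchymal transition genes, 2 were higher and 1 lower (3 and 0 relative to all genes, 0.11 above, percentile 75.6), with Snai2 at 2.60 and 5.81 CPM.

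Across genes, the ratio also followed transcript length. In clusters 1 and 5, the shortest of 10 equal groups of genes by transcript length (median 999 bp) had a median log2 ratio of 0.16 and the longest (median 8409 bp) one of -0.45, and clusters 6 and 8, compared between libraries, showed the same order. With the trend removed from the whole class, 1003 genes were lower, the Hippo list median was 0.00 (percentile 56.8), the Notch median 0.04, the DNA repair median 0.02 and the G1/S median 0.07. The median of YAP targets was -0.22, and those of interferon (0.28), dissociation stress (0.38) and platinum handling (0.37) stayed above 0.

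**Figure D2:**
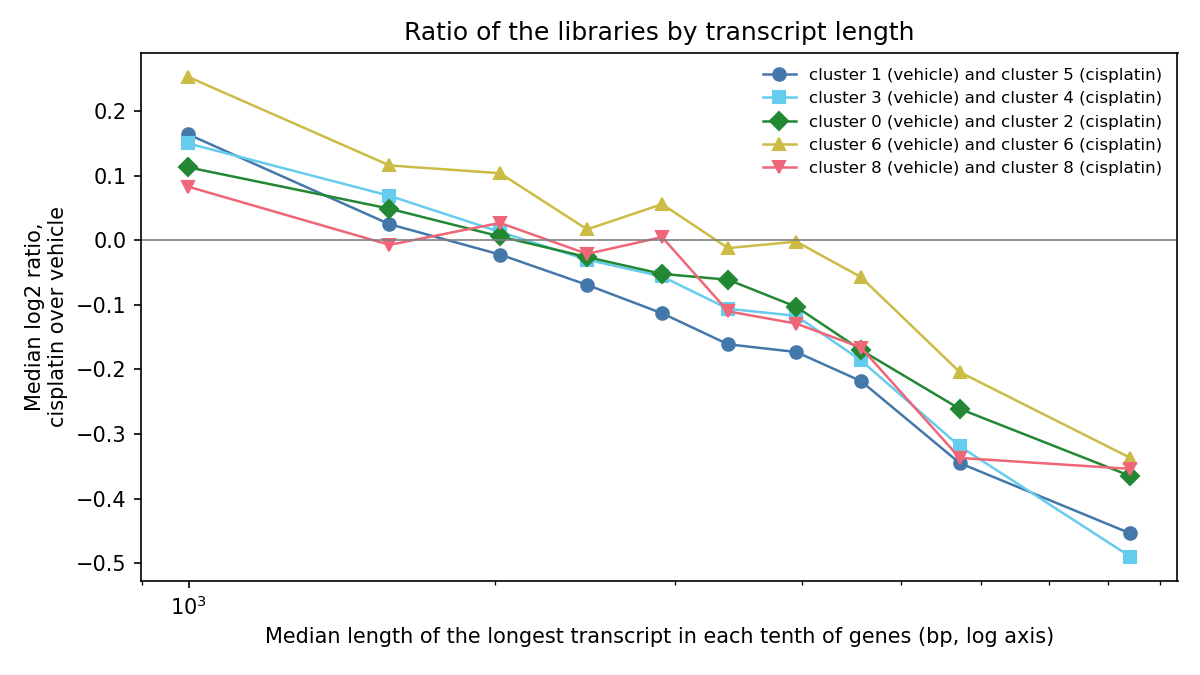
Median log2 ratio of CPM, cisplatin over vehicle, in 10 equal groups of genes by transcript length (bp, log axis) for the 3 pairs of clusters and for clusters 6 and 8, with a line for each. In clusters 1 and 5 the median runs from 0.16 at 999 bp to -0.45 at 8409 bp.

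**Figure D3:**
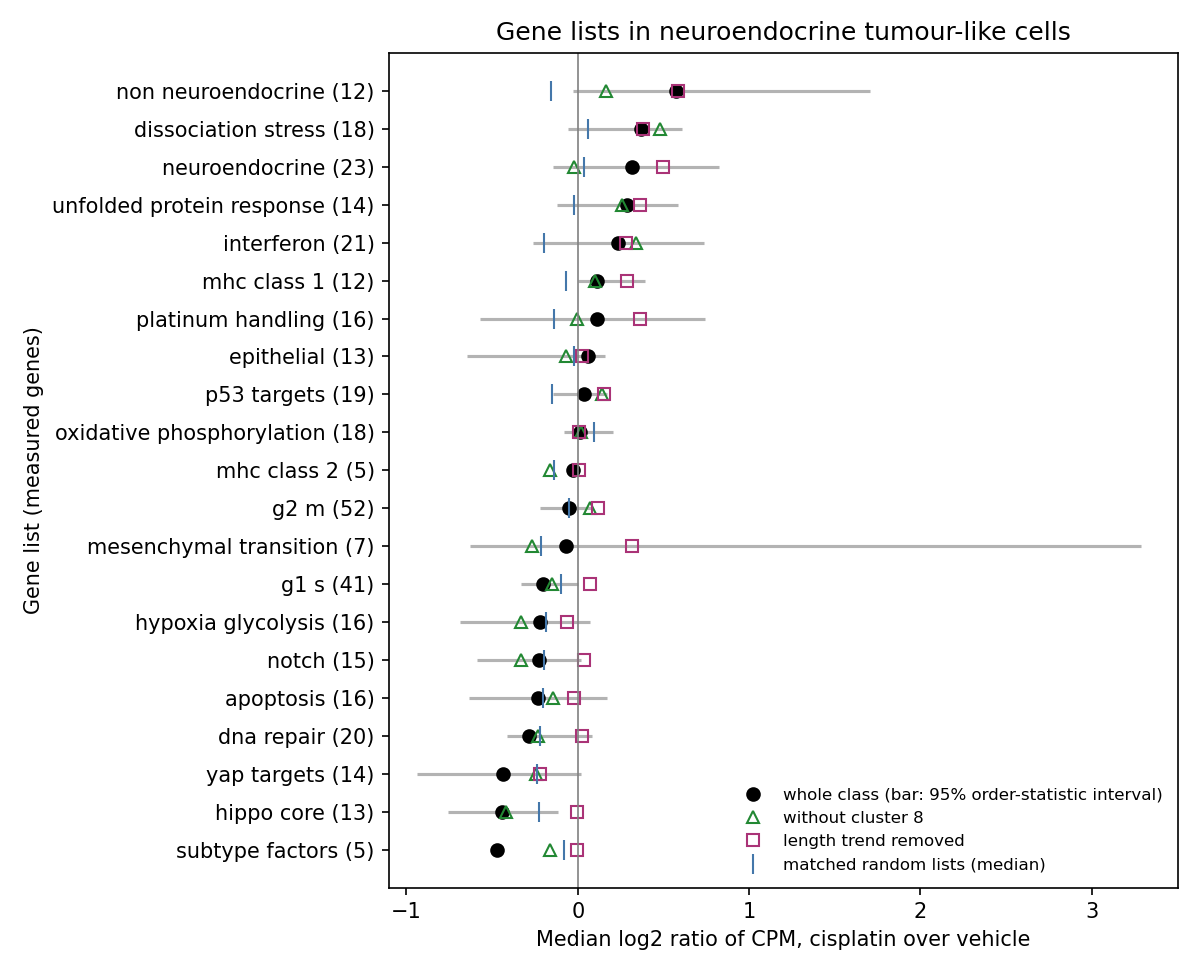
Median log2 ratio of CPM, cisplatin over vehicle, of each gene list in neuroendocrine tumour-like cells (black points; grey bars, 95% order-statistic interval over members, not shown for lists too small to give one). Green triangles leave out cluster 8, purple squares remove the trend with transcript length, and blue ticks mark the median of matched random lists, so that the neuroendocrine list moves from 0.31 to -0.02 without cluster 8.

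Over all kept barcodes, which answers the comparison as the series states it, most lists kept the direction they had in tumour-like cells. Of 13446 measured genes, 1088 were higher and 2912 lower, with a median log2 ratio of -0.16. Of 5 MHC class II genes 4 were higher, with a median 1.29 above that of all genes, against 1 of 5 and 0.14 above in tumour-like cells. The barcodes left out of that class held 3 macrophage-marked ones in cisplatin and 0 in vehicle. Cd74, H2-Aa and H2-Ab1 are among the genes that lead cluster 9, but that cluster held more vehicle than cisplatin barcodes. Which barcodes carry the higher class II level was not tested. Of 9 mesenchymal transition genes 2 were higher and 4 lower (2 and 2 relative to all genes), with a median 0.24 below that of all genes. S100a8, a neutrophil calcium-binding protein, was the lowest gene at 45.3 CPM in vehicle (43.1 to 47.7) and 0.872 CPM in cisplatin (0.564 to 1.29), and it leads the small cluster 9, which held 15 vehicle and 2 cisplatin barcodes. The interferon list had a median 0.36 above that of all genes (7 higher and 2 lower of 21; 8 and 0 relative to all genes), the YAP target list 0.28 below (1 higher and 6 lower of 14; 1 and 5), the p53 target list 0.21 above (2 higher and 1 lower of 19; 2 and 0) and the neuroendocrine list 0.46 above (9 higher and 3 lower of 23; 10 and 2).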

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

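The pairs of like clusters and the step on barcodes with markers of other cell types were chosen after the data were seen.

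Genes of the G1/S transition, which are needed for DNA replication, differed in direction between the pairs of like clusters. Their median log2 ratio, cisplatin over vehicle, was -0.363 in clusters 1 and 5, -0.224 in clusters 3 and 4, and 0.218 in clusters 0 and 2, and the difference between the pairs was not tested. Of 41 members, 0 were higher and 11 lower in clusters 1 and 5, 1 higher and 6 lower in clusters 3 and 4, and 13 higher and 0 lower in clusters 0 and 2. Relative to the median of all genes these were 0 and 8, 2 and 2, and 15 and 0. The G2 and mitosis list had 0 higher and 13 lower of 52 (1 and 6 relative to all genes) in clusters 0 and 2, where its median was -0.36. The clusters of a pair were taken to be of like cell cycle phase, and the match was not measured. Cluster 0 had Mki67 and Cenpf among its leading genes, and cluster 2 had Ccnb1 and Cdc20. For cell cycle lists, an imperfect match of phase therefore cannot be told apart from a difference between the libraries.

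Barcodes with markers of other cell types stood outside the comparisons and lay above the limit for a count of 0. They made up 0.708% of the vehicle library (26 barcodes; 0.463 to 1.04%) and 0.166% of the cisplatin library (7 barcodes; 0.067 to 0.342%), although the cells were sorted for GFP. By marker set, vehicle and cisplatin held 9 and 1 T cell, 5 and 1 endothelial, 3 and 0 neutrophil, 0 and 3 macrophage, 3 and 0 alveolar type 2, 2 and 1 B cell, 2 and 0 club, 2 and 0 monocyte, and 0 and 1 alveolar type 1 barcodes.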

How the results depend on the processing

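Leaving out cluster 8, the pairs of clusters, removing the trend with transcript length, adding cluster 6 to the class, removing high Scrublet scores, keeping barcodes with markers of other cell types and thinning cells before summing were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because both samples carry replicate number 1, given in accession order, and each group is 1 library. Of the values that answer a comparison, 328 were counted as kept, 54 as moved and 2 as reversed. Of single genes and lists these counts were 2511, 703 and 15. A value counted as kept need not have kept its sign. Removing no doublets changed nothing, since none had been removed, and another fold limit cannot move a median. Values under such settings were bound to be kept, so the number kept does not measure how stable the results are. A value was counted as reversed only if its own interval left out 0 and the alternative had the other sign, at any size. Other turns of sign were counted as moved or kept, as for the Notch median without the length trend, so more signs turned than were counted. The cause was not tested for the values that follow, except where fewer or more genes or cells enter by construction.

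Under the stricter planned filter the neuroendocrine tumour-like share, vehicle, was 88.7%, the Yap1 share, vehicle, 0.144%, the cycling share, vehicle, 38.9% and the cycling share, cisplatin, 46.5%. The neuroendocrine tumour-like share, cisplatin, was 96.3% at resolution 0.3. At resolution 1.0 the vehicle and cisplatin shares were 90.8% and 96.7%. The cisplatin share was 97.4% with all variable genes. Without the highest 6% of Scrublet scores the shares were 89.5% and 96.1% (cycling 39.4% in vehicle), and with cluster 6 added 99.3% and 99.8%. Unthinned, the Yap1 shares were 0.866% and 0.473% and the cycling shares 64.6% and 57.6%. The cycling shares were 65.2% and 66.2% with at least 1 UMI, and 26.2% and 32.2% with at least 4.

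Without cluster 8, 711 genes were higher, and the log2 ratios of Tubb3 (-0.17) and Chga (-0.22) reversed. In clusters 1 and 5, 579 genes were higher, the p53 target median was 0.18 and the G1/S (g1_s) median -0.36, and Tubb3 (-0.22), Cd74 (-0.11) and Chga (-0.14) reversed. In clusters 3 and 4, 457 genes were higher, the neuroendocrine median was -0.17, and Tubb3 (-0.69), Isg15 (-0.26) and Chga (-0.34) reversed. In clusters 0 and 2, 660 genes were higher, the G2 and mitosis (g2_m) median was -0.36, and the G1/S median (0.22), Tubb3 (-0.10), Tead3 (0.039), Mycl (0.15), Ddit3 (-0.16) and Chga (-0.079) reversed.

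With the length trend removed from the tumour-like class, 1003 genes were lower, the Notch median was 0.036 and the G2 and mitosis median 0.12, and the G1/S median (0.074) and Nfib (0.036) reversed. Over all kept barcodes, 1070 genes were lower and the medians were 0.043 (Notch), 0.14 (p53 targets), 0.063 (G1/S) and 0.14 (G2 and mitosis), with the Hippo median (hippo_core) reversed at 0.021. With median-of-ratios size factors, 1885 genes were lower in the class and 1876 over all kept barcodes, the p53 target medians were 0.20 and 0.20, and the G2 and mitosis medians 0.10 and 0.15. With TMM the p53 target median over all kept barcodes was 0.18. With a floor of 1 UMI, the genes higher, neuroendocrine tumour-like, were 3149 and the genes lower, neuroendocrine tumour-like, 5250, and the genes higher, all kept barcodes, were 3138 and the genes lower, all kept barcodes, 5445. With a floor of 200 UMIs, 686 and 691 genes were higher. With a 2-fold limit, 527 were higher and 923 lower in the class, and 516 and 959 over all kept barcodes. Depth limits what can be said of Yap1 and Wwtr1, with 30 and 0 UMIs in vehicle and 19 and 3 in cisplatin.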

Other observations

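The tests on transcript length, depth and abundant genes were set before their results were seen, the first of them after noticing which genes were lower; the tests on doublets, barcode swapping, different animals, free Yap1 RNA, imprinted genes and whole chromosomes were chosen after the data were seen.

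Cluster 8 differed from the other neuroendocrine tumour-like cells in lists that had been left out of the clustering. In the cisplatin library, 34 of 52 genes of G2 and mitosis were lower in cluster 8 and 0 higher (median log2 ratio -0.71), with Top2a at 354 CPM in the other cells and 166 CPM in cluster 8. In vehicle, where cluster 8 held only 17 cells, 32 of 51 were lower and 0 higher (-0.74). The share of cycling cells in cisplatin was 37.7% in cluster 8 and 46.0% in the other cells when thinned. Unthinned, the order turned, with 61.4% and 56.8%. In vehicle these shares were 29.4% and 41.9% thinned, and 76.5% and 64.5% unthinned. The p53 target list was lower in both libraries (-0.56 in cisplatin, -0.44 in vehicle), with Cdkn1a at 532 and 179 CPM in cisplatin and at 426 and 110 CPM in vehicle. Of 12 measured YAP targets in cisplatin, 7 were lower and 1 higher (median -1.20), and of 20 interferon genes 13 were lower and 1 higher (-0.99). The other cells there include cluster 7, which is led by interferon-response genes. Dissociation stress was also lower (-0.54 in cisplatin, -0.81 in vehicle). The left-out lists that stood highest in cisplatin were hypoxia and glycolysis (0.26), the unfolded protein response (0.25) and MHC class I (0.20). In vehicle these were at 0.16, -0.18 and 0.37.

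The 17 vehicle and 754 cisplatin cells of cluster 8 shared some hormone and transcription factor genes and not others. Hhex, an endodermal transcription factor, was at 599 CPM in the vehicle cells (499 to 714) and 523 CPM in the cisplatin cells (505 to 541), while Sst (somatostatin) was at 5971 and 978 CPM and Pnoc (prepronociceptin) at 24 and 712 CPM. In cluster 6, which held cells of both libraries, 24 of 51 genes of G2 and mitosis were higher in cisplatin and 3 lower (median 0.52). Of 14 unfolded protein response genes there, 6 were lower and 0 higher (-0.36), with Trib3 at 233 and 120 CPM, and Cxcl10 was at 37.2 CPM (28.3 to 48.0) and 277 CPM (249 to 306).

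More genes were lower than higher in the cisplatin library across the 3 pairs of clusters (385 lower and 101 higher of 5604 in all 3). Lower depth was tested by thinning cells to 3000 UMIs and leaving out those below, and the lower genes were still 4.598 times the higher ones. Thinning hardly changes the proportions of genes in summed counts, so this result cannot decide whether depth played a part. A few abundant genes were argued against, since the median log2 ratio without the 100 most abundant genes was -0.163. Centring each pair on its median left 272 lower and 153 higher. With a trend on transcript length removed as well, 127 of those 272 genes (46.69%, close to the 50% bound set for it) stayed lower and 118 of the 153 stayed higher, and 140 were lower and 171 higher in all, a balance that the step itself favours, so the trend may account for the excess of lower genes but not for each of them. What made the trend was not tested, and RNA quality, library preparation and a biological difference by treatment remain open.

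Cluster 8 held a higher share of the cisplatin library. Doublets with the other tumour cells were argued against by 44 of 1782 genes of at least 100 CPM in the other cells that lay more than 4-fold below that level in cluster 8, a test that replaced one on UMIs per cell, whose ratio was 1.335. Swapped barcodes were argued against by 0 of the 17 vehicle barcodes occurring in the cisplatin library, and a gain or loss of a whole chromosome by a largest autosome difference of 0.065. Different tumours or animals cannot be told apart from treatment with 1 library per group, so the treatment may or may not be behind the share.

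Few cells had a Yap1 UMI. The share in cluster 6, 0.282% of thinned cells over both libraries (1 of 355; 0.007 to 1.56%), lay inside the interval of the tumour-like cells (14 of 6998; 0.20%; 0.109 to 0.335%), which free RNA in the droplets could give. Cluster 6 has no type and its single cell with a UMI decides nothing, so expression and free RNA cannot be told apart, and no biological explanation was tested.

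Igf2 and Meg3 are imprinted. The hypothesis that imprinted genes as a set differed more between the libraries than other genes was not borne out for their median. Their median absolute log2 ratio lay at percentile 66.92 of random lists in clusters 1 and 5, and at 86.89 and 94.75 in the other pairs. A median does not show whether a part of the set differed. Of 29, 26 and 28 measured imprinted genes, 5, 6 and 5 were higher and 6, 5 and 6 lower, with 1 CPM added. Of all measured genes in these pairs, 4.84%, 4.46% and 5.89% were higher and 22.2%, 21.5% and 18.6% lower in CPM. These counts were not tested.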
